A study of Gallus gallus with 4 samples.

How the data were processed

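Total RNA from 50 mg of duodenum was extracted, brought to a common concentration and pooled within a group, and 200 ng was labelled with Cy3 for hybridization to 1-colour Agilent chicken arrays (design 026441), per the labels' protocols. Signals were read with Agilent Feature Extraction 11.5.1.1, per the file headers, and all 4 arrays came from 1 slide and 1 scan, so slide and scan cannot differ between groups. The deposited scanner values are spot intensity values on a linear scale, background-subtracted and detrended within each array per the file headers, and not scaled between arrays. The deposited series matrix holds log2 values. Each of its columns followed the log2 processed signal of the same array minus the 75th percentile and minus the median of the 4 arrays per probe, with a correlation from 0.9998 to 1, so scale, centring and direction are known, and its column medians were -0.04, -0.01, -0.01 and 0.10. The deposited files also carry other columns, the flags of Feature Extraction for spots well above background, saturated or outlying.

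Arrays were grouped by the labels into high FE (2) and low FE (2), and the arrays of a group were kept as 2 samples, as planned. The processed signal was taken to log2, spots of a probe were averaged, control spots were left out and spots with an outlier flag were set missing, which left out 53 probes. No spot was saturated. Each array was scaled by subtracting its 75th percentile over non-control probes. Of 43603 probes, 35731 were tested, those well above background on both arrays of at least 1 group. High minus low FE was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2 residual and 3.70 prior degrees of freedom), adjusted by Benjamini-Hochberg and called at adjusted p under 0.05 with an absolute log2 fold change of at least 1. A gene was represented by its brightest tested probe. Folds are on the scaled log2 signal.

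Probe identifiers were matched without versions to the RefSeq genes of assembly GRCg7b, used for names and for Z and W membership only, since the array grid was built on galGal3. A gene was found for 11935 probes, giving 5382 genes, of which 5020 were tested. The other 14692 Ensembl transcript probes and 16976 probes with other identifiers stayed unnamed, among them 259 of the 423 called probes, so the named genes are a part of what the arrays measured.

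Gene lists for the tissue and for neighbouring cell types were written before the data were examined, as were the tests, the main settings and the rule for named genes. That rule took the 12 largest changes in each direction among called genes well above background in the brighter group, filled up with the smallest p where fewer passed. It added up to 4 members of each list with the smallest p, and the brightest members of the pancreas, erythrocyte, hepatocyte and W-linked lists. FGA, ITIH2, CRPL1, F2, FABP1, FABP2, RBP2, SLC5A1, SLC15A1, BF1 and BF2 are named outside it, after their values were seen. Some genes that the rule takes are not reported here. Lists of at least 5 tested genes were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. Members were counted as risen or fallen at adjusted p under 0.05 over all genes at any fold, and also adjusted over the list alone. A second liver list of 70 genes, 16 of them tested, was written later, without sight of its values.

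The limma step was tested on simulated arrays of 35731 probes in which 200 probes changed. With variances drawn from the fitted prior, it recovered 0% of changes of 1 on the log2 scale, 1.49% of changes of 2 and 66.7% of changes of 4, and 5 of 50 calls were false. With each probe's shrunken variance it recovered 0%, 50.7% and 100%, with 14 false calls among 114, and with each probe's residual variance it made 0 calls. Over 4820 simulated genes that varied independently of each other, camera found the 1 shifted list of 20 genes and none of 30 unchanged lists. In the data the estimated correlation within called lists ranged from -0.03 for brush border enzymes to 0.59 for ribosomal genes. The simulation therefore cannot say how often camera calls unchanged lists of correlated genes.

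Alternatives planned before the data were examined were quantile normalization, normexp background correction, other filters on dim probes, saturated probes left out, the series matrix values, a replicate block, a variance trend with a robust prior, each array left out, the mean of a gene's probes, other thresholds, Z and W genes left out and other list tests. Normexp was planned on mean spot signals and was run, with an offset of 50, on median spot signals, the ones read here. That change, the 2 high FE arrays averaged as 1 sample, liver genes left out and other scalings of the sex chromosome and replicate values were chosen after seeing the data.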

Results

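Gene expression in the duodenum, the first segment of the small intestine, was measured in coloured broiler chickens aged 35 days that differed in feed efficiency (FE). The design used residual feed intake, the feed eaten beyond what growth and maintenance predict, to separate the birds, and set a high FE group against a low FE control group. Each group gave 2 one-colour arrays, called here replicates 1 and 2. By the design text, RNA of 4 to 5 birds per group was pooled and each pool was divided. The labels instead give the sexes of 2 birds per array, and these differ between the low FE arrays, as did the signals of sex-linked genes. By the labels the high FE arrays and low FE replicate 1 were female, and low FE replicate 2 was 1 male and 1 female. Sex is thus partly confounded with the comparison of high with low FE. The p-values measure the spread between arrays, and how much of it is spread between birds is unknown. Of 43603 probes, between 79.3% and 87.8% were well above background on an array. The 75th percentile of the signal was 1739 and 1492 on the high FE arrays, 2194 on low FE replicate 1 and 699 on low FE replicate 2. With 2 arrays per group, the number of arrays limits the precision.

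The comparison of high with low FE asked which duodenal transcripts differed with feed efficiency. Transcripts of proteins that the liver secretes into plasma were far higher on both high FE arrays. AMBP, the precursor of alpha-1-microglobulin and bikunin, rose by 9.90 ± 0.33 on the log2 scale (SE, n = 2 arrays per group, adjusted p = 2.35e-04), and RBP4A, a plasma retinol carrier, was at least 561-fold higher (adjusted p = 2.35e-04). TTR, which carries thyroid hormone, rose by 9.37, and the fibrinogen chains FGG and FGB rose by 9.05 and 8.50. PIT54, a haemoglobin-binding plasma protein of birds, rose by 8.45, and ALB, serum albumin, rose by 7.43 ± 0.31. AMBP and RBP4A were well above background on 1 of the 2 low FE arrays. For AMBP the bound equals the estimate, 958-fold, its low FE signals being used as measured. The 95% interval of the AMBP change began at 9.09 on the log2 scale.

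Further genes among the 12 largest increases were the nucleotide-synthesis enzyme PRPS2 (at least 168-fold higher, well above background on 1 low FE array), the beta-defensin AvBD9 (8.26) and the secreted phosphoprotein SPP2 (8.08). MBL2, a lectin of the complement system, SPIA4 and SPIA5 were not well above background on either low FE array. They were at least 146-fold, at least 82.6-fold and at least 68.8-fold higher with high FE. For such genes the bound sets the mean of the brighter group against the lowest signal that was well above background on each array of the dimmer group, or the probe's own signal where that was higher.

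Fewer genes were lower with high FE. GAL3ST2, a galactose sulfotransferase, was not well above background on either high FE array and was at least 133-fold lower there (adjusted p = 2.94e-04), with signals of 0.88 and 1.28 on the low FE arrays. The histone gene H2AFX and the melanocortin receptor MC5R were also not well above background on the high FE arrays and were at least 3.17-fold and at least 1.78-fold lower, and neither passed under either normexp setting, nor MC5R with a variance trend. MTIF3, a mitochondrial translation initiation factor, fell by 2.81, the superoxide-producing oxidase NOX1 fell by 2.44 and FANCA, of the Fanconi anaemia DNA repair pathway, fell by 2.31. Without the filter on dim probes MTIF3 and FANCA did not pass, nor did FANCA without high FE replicate 2. None of MTIF3, NOX1 and FANCA passed under normexp with 75th percentile scaling. GSC, DUSP4 and the phospholipid flippase ATP8B1 fell by 1.94, 1.82 and 1.79. None of them passed when either high FE array or the filter on dim probes was left out. The same held with a variance trend and under normexp with 75th percentile scaling. GSC and DUSP4 also did not pass under normexp with quantile normalization. ATP8B1 also did not pass with quantile normalization, or when all 4 arrays had to be above background. The next genes in this direction did not pass: TNFSF10 (-1.95, adjusted p = 0.0553), the chloride channel CFTR (-1.92, adjusted p = 0.0702) and ART1L2 (-1.66, adjusted p = 0.0844).

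In total, 423 of 35731 tested probes passed limma with Benjamini-Hochberg adjusted p under 0.05 and a 2-fold change, of which 375 were higher and 48 lower with high FE. At an unadjusted p under 0.05 there were 4555 probes. Among 5020 named genes, 95 passed, 86 higher and 9 lower, and 586 had an unadjusted p under 0.05. No probe passed after normexp background correction with 75th percentile scaling, where 12 genes did, and with a replicate block 1511 probes passed. Without low FE replicate 1 the count was 6185 probes, 2387 of them higher, and without low FE replicate 2 it was 4940, 2617 of them higher.

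**Figure D1:**
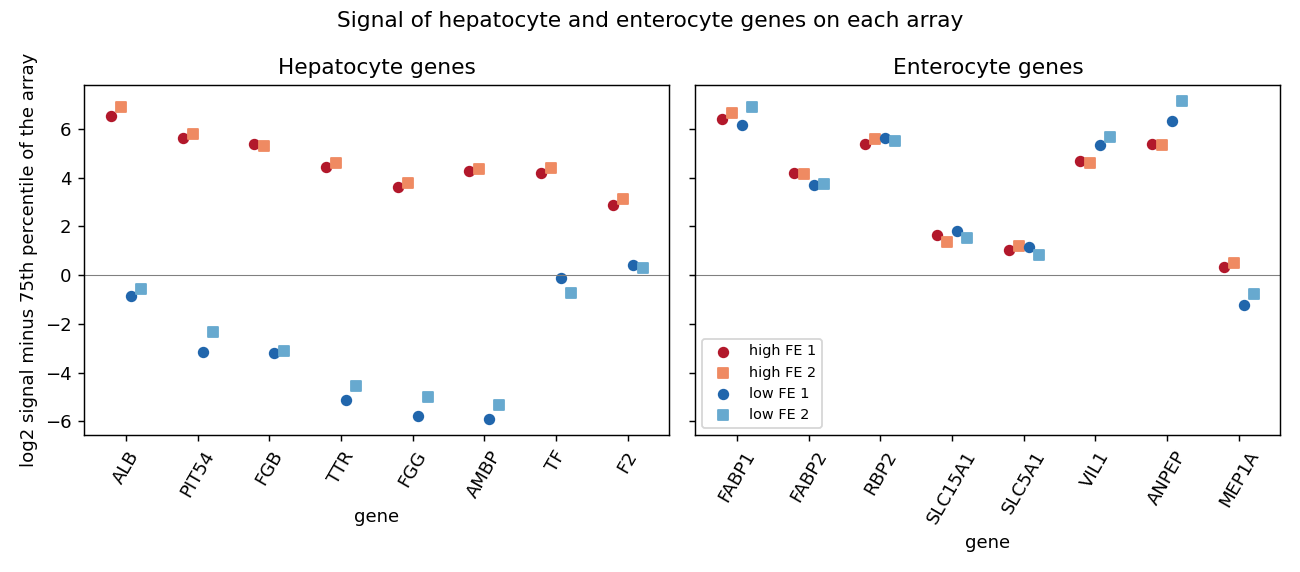
Signal of 8 hepatocyte genes (left) and 8 enterocyte genes (right) on each of the 4 arrays, as log2 signal minus the 75th percentile of the array, with 1 point per array. The hepatocyte genes lie apart between the groups, as for ALB with a log2 fold change of 7.43, while the enterocyte genes go both ways, from -1.37 for ANPEP to 1.43 for MEP1A, and none passed.

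Of 16 measured hepatocyte markers, 11 rose and 5 did not pass, and 14 rose when adjusted over the list alone. The median log2 fold change was 4.51 (camera adjusted p = 3.85e-20, and adjusted p = 0.549 with an estimated correlation). Besides the genes above, FGA, the iron carrier TF, ITIH2, CRPL1 and the prothrombin gene F2 rose, by 7.85, 4.72, 4.31, 2.86 and 2.64. APOH and the urea cycle enzyme ASS1 (-0.56) were bright but did not pass. APOH had 1.24 at its brightest probe and 6.51 at its other probe, which passed among probes, and it passed with the mean of both, at 3.88. The list took 0.653% and 0.692% of all signal on the high FE arrays against 0.0250% and 0.0390% on the low FE arrays, and 15 of its members were above background on both low FE arrays.

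Among lists on lipids, camera called lipogenesis and lipid absorption as higher, on the arrays where the hepatocyte median was 4.51, and did not call cholesterol biosynthesis (median 0.38) or fatty acid oxidation and PPAR targets (median -0.20). On cholesterol biosynthesis the low FE arrays differed by a median of 1.48, and without low FE replicate 2 the list was called as higher (adjusted p = 1.23e-04), as fatty acid oxidation was as lower (adjusted p = 0.00761). In the lipogenesis list 2 of 12 genes rose, or 4 adjusted over the list alone. The 2 were THRSP and ELOVL2. THRSP, a regulator of lipogenic genes, rose by 3.80 (from 3.13 to 4.48 without 1 low FE array). ELOVL2, which elongates polyunsaturated fatty acids, was at least 12.3-fold higher, a bound because neither low FE array was well above background. Over the alternative settings ELOVL2 went as low as 1.31 on the log2 scale. THRSP and ELOVL2 did not pass under normexp with 75th percentile scaling. The list had a median of 0.86 (camera adjusted p = 0.00320, and adjusted p = 0.582 with an estimated correlation). For lipid absorption and lipoprotein assembly, 0 of 17 genes passed over all genes and 5 rose adjusted over the list alone, with a median of 0.45 (camera adjusted p = 0.00528, and adjusted p = 0.549 with an estimated correlation). Its leading members, none of them passing with all arrays, were APOB (3.26, from 2.37 to 4.15 without 1 low FE array), APOA4 (2.98, from 1.81 to 4.15), APOA1 (2.30, from 1.69 to 2.91) and the fatty acid translocase CD36 (1.94, with 0.12 at another probe). The enterocyte fatty acid carriers FABP1 (0.01) and FABP2 (0.45) did not pass.

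In the xenobiotic metabolism list 2 of 32 genes rose, or 3 adjusted over the list alone. Among them CYP1A2, a monooxygenase of drugs and aromatic amines, rose by 5.10, on the arrays where the hepatocyte median was 4.51, with 2.57 at its other probe. The list had a median of 0.48 (camera adjusted p = 0.00970, and adjusted p = 0.549 with an estimated correlation). Without low FE replicate 2 its camera adjusted p was 0.374.

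Stromal and extracellular matrix markers had a median of 0.65, with 27 of 31 positive, beside the hepatocyte median of 4.51. None passed over all genes and 3 rose adjusted over the list alone. The members with the smallest p were the proteoglycan LUM (1.61), THBS1 (1.60), FBLN1 (1.55, with -0.48 at its other probe) and the matrix protease MMP2 (1.26). The camera adjusted p was 2.54e-06, and adjusted p = 0.582 with an estimated correlation.

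Among blood cell lists, camera called the erythrocyte and the myeloid list as higher, on the arrays with the hepatocyte median of 4.51, and did not call T and NK cell or B and plasma cell markers (median 0.23 each). In the erythrocyte list 1 of 15 genes rose, RHAG, of the Rh blood group complex (at least 3.92-fold, not well above background on either low FE array), which did not pass under either normexp setting. Adjusted over the list alone, 5 rose and 1 fell. The globins HBAD (1.57), HBBA (1.05) and HBA1 (1.05) did not pass over all genes, and the list had a median of 0.40 (camera adjusted p = 0.0419, and adjusted p = 0.582 with an estimated correlation). In the myeloid and heterophil list 1 of 26 genes rose, or 5 adjusted over the list alone. It was LECT2 (2.20), a chemotactic factor that hepatocytes also secrete, which did not pass when either high FE array or the filter on dim probes was left out, and the list had a median of 0.28 (camera adjusted p = 0.0339, and adjusted p = 0.707 with an estimated correlation). Without low FE replicate 1 the camera adjusted p was 0.299 for the myeloid and 0.212 for the erythrocyte list, and for the latter 0.147 without high FE replicate 2 and 0.0507 without low FE replicate 2.

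Camera called the lists of interferon-stimulated genes and antigen presentation as lower with high FE, on the arrays where the hepatocyte median was 4.51, and did not call cytokines (median -0.10). For interferon-stimulated genes 0 of 12 passed over all genes and 0 adjusted over the list alone, and 0 of 12 had a positive fold change. The median was -0.83 (camera adjusted p = 3.75e-04, and adjusted p = 0.549 with an estimated correlation). The transcription factors IRF9 (-1.02) and IRF1 (-0.87) had the smallest p, and IFI27L2 (-1.05) the lowest fold change. For antigen presentation, likewise 0 of 12 passed either way, with a median of -0.70. B2M, the light chain of MHC class I, had -1.10, the MHC class II gene BLB1 -1.17 (-0.21 at another probe) and the peptide transporter genes TAP1 -0.90 and TAP2 -1.17 (camera adjusted p = 0.00128, and adjusted p = 0.549 with an estimated correlation). The class I genes BF1 and BF2 had -0.16 and 0.00 at their brightest probes and -1.65 and -1.54 at their lowest, and their probes differed between the low FE arrays by amounts from -2.75 to -0.02 (replicate 2 minus replicate 1).

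Camera also called brush border, pancreas, oxidative phosphorylation and ribosomal lists as lower, beside the hepatocyte median of 4.51, with no member passing over all genes. It did not call sugar and amino acid transporters, the proteasome or heat shock genes, with medians of 0.12, 0.10 and 0.05. Among brush border enzymes 0 of 9 passed over all genes, while 1 rose and 2 fell adjusted over the list alone. The median was -0.39, with the brush border myosin MYO1A at -1.64, the aminopeptidase ANPEP at -1.37 and the protease MEP1A at 1.43 (camera adjusted p = 0.0455, and adjusted p = 0.549 with an estimated correlation). For exocrine pancreas markers 0 of 14 passed either way, with a median of -0.48 (camera adjusted p = 0.00970, and adjusted p = 0.549 with an estimated correlation). They included the amylase gene AMY2A (-0.87) and CTRL (at least 2.36-fold lower, not passing, well above background on 1 of 2 high FE arrays). For oxidative phosphorylation 0 of 35 passed either way, with a median of -0.17 (camera adjusted p = 0.00990, and adjusted p = 0.549 with an estimated correlation). Cytosolic ribosomal proteins, with 0 of 48 passing either way, had a median of -0.24 (camera adjusted p = 0.0122, and adjusted p = 0.732 with an estimated correlation). Their direction turned without low FE replicate 2, with an adjusted p of 0.839, and without high FE replicate 1 it was 0.109. Without low FE replicate 1 the adjusted p was 0.212 for the brush border and pancreas lists and 0.0961 for oxidative phosphorylation, without high FE replicate 2 it was 0.0524 for brush border and oxidative phosphorylation, and without high FE replicate 1 it was 0.118 for brush border.

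**Figure D2:**
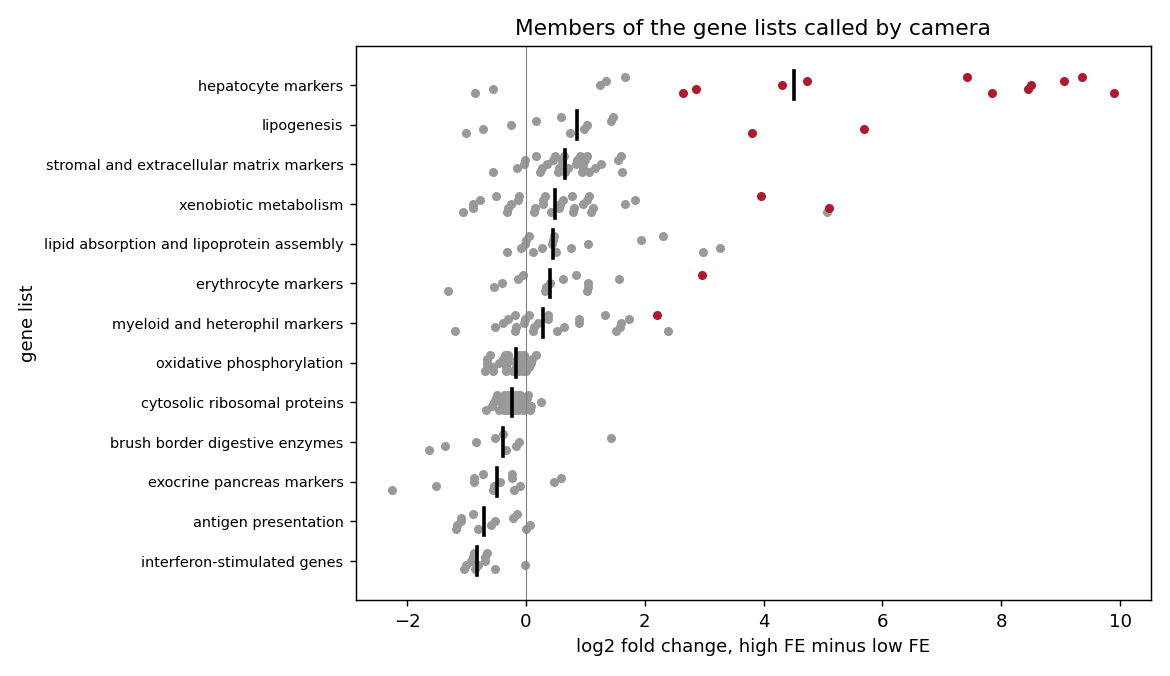
Log2 fold changes (high FE minus low FE, horizontal axis) of the tested members of the 13 gene lists called by camera, with red points for adjusted p under 0.05 over all genes, grey points for other members and black bars for list medians. The hepatocyte markers have a median of 4.51, and the interferon-stimulated genes one of -0.83.

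Single genes also changed in lists that were not called. In growth, insulin and appetite signalling 1 of 39 genes rose and 1 fell (camera adjusted p = 0.179). The AMP-activated kinase subunit PRKAA2 rose 9.03-fold with its low FE signals as measured (well above background on 1 of 2 low FE arrays). Its 95% interval began at 2.49 on the log2 scale. Normexp with 75th percentile scaling gave PRKAA2 0.985 on that scale, which did not pass. MC5R was lower, as given above. The tight junction gene CLDN1 rose by 3.25 at the brightest of its 3 probes, which ranged from 0.44 to 3.25, in a list of negative median, -0.47, whose camera and fry directions differed (camera adjusted p = 0.280). The phosphate transporter SLC34A2 rose by 2.49 among mineral and metal handling genes (camera adjusted p = 0.284, median -0.31 and mean 0.02). Its other probe had 0.56, and with the mean of both probes SLC34A2 did not pass (1.53, adjusted p = 0.0578). CD72 rose by 2.62 among B and plasma cell markers (camera adjusted p = 0.348). DUSP4 was the 1 immediate early gene that fell (camera adjusted p = 0.252).

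In the other lists no member passed over all genes. Among sugar and amino acid transporters, the glucose cotransporter SLC5A1 had 0.12 and the peptide transporter SLC15A1 -0.18 (camera adjusted p = 0.562). The camera adjusted p was 0.0707 for enteric neuron and glia markers, 0.0808 for fatty acid oxidation and PPAR targets, 0.169 for intestinal stem and progenitor markers, 0.252 for the cell cycle and 0.280 for cholesterol biosynthesis and for the unfolded protein response. It was 0.292 for T and NK cell markers, 0.325 for enteroendocrine markers, 0.332 for cytokines, 0.334 for smooth muscle markers, 0.509 for antioxidant defence, 0.514 for heat shock genes, 0.618 for the circadian clock and 0.917 for the proteasome. Adjusted over the list alone, 6 growth and insulin genes rose and 2 fell, 4 mineral handling genes rose and 5 fell, and 4 cytokine genes fell. Enteric neuron and immediate early lists had 1 gene in each direction, the stem and progenitor list had 1 that fell, the junction, B cell and antioxidant lists had 1 that rose, and the other lists had none. Goblet cell and W-linked lists had 4 tested genes each, too few for camera. Of 33 lists tested, 13 were called by camera, 0 with an estimated correlation and 1 by fry, the hepatocyte markers (adjusted p = 0.0332). With an estimated correlation camera rests on 2 residual degrees of freedom, and even the hepatocyte list had an unadjusted camera p of 0.0238. That version thus had little power, and its lack of calls decides little about a list.

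The arrays of a group were compared with each other to set the spread behind these tests. The high FE arrays correlated at r = 0.990 across probes, which are not independent replicates, with a median absolute log2 difference of 0.20 and 687 probes at least 2-fold apart. The low FE arrays correlated at 0.945, with a median difference of 0.54 and 7849 such probes, while pairs from different groups had between 5314 and 7331.

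W-linked and Z-linked genes were read on each array, because the labels give 3 arrays as female and low FE replicate 2 as 1 male and 1 female. HINTW, a multicopy gene of the W chromosome, which only hens carry, was lower in low FE replicate 2 by over 5 on the log2 scale for 7 of 8 probes, 4 of which were not well above background there. The brightest HINTW probe fell by 1.49. The mean deviation of the W-linked list from the other 3 arrays was -0.59 for low FE replicate 2, and 0.09, 0.42 and 0.09 for high FE replicates 1 and 2 and low FE replicate 1. Over 438 probes of Z-linked genes, which males carry in 2 copies, the median deviation was 0.39 in low FE replicate 2 and -0.13, -0.20 and -0.13 in the others. These are descriptions of single arrays with no test.

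**Figure D3:**
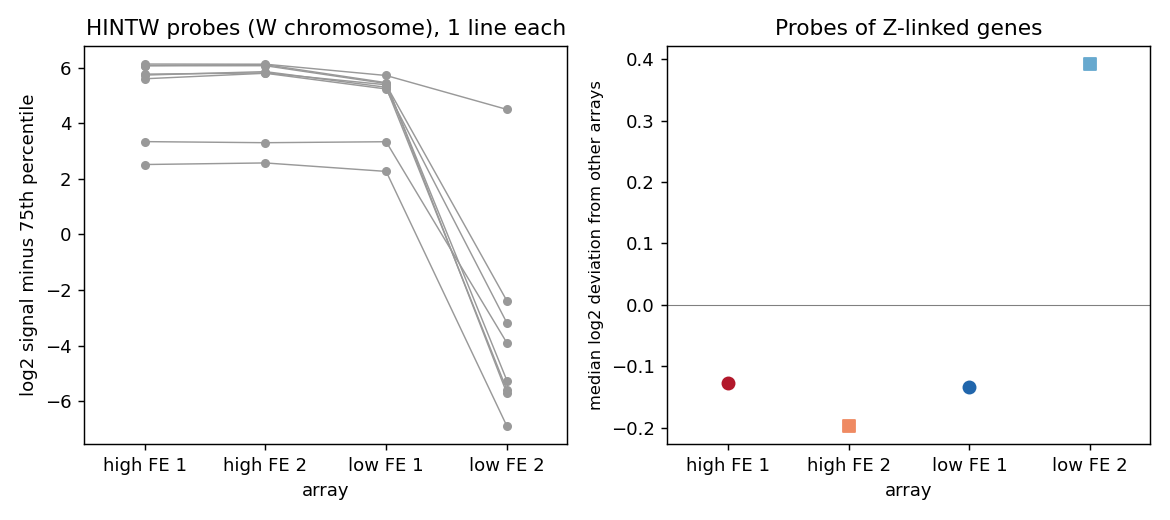
Log2 signal of the 8 HINTW probes on each array, with lines joining the values of a probe (left), and the median log2 deviation of probes of Z-linked genes from the other 3 arrays (right). In low FE replicate 2 all HINTW probes are lowest and the Z-linked median is 0.39.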

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

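The normexp settings, the averaged high FE arrays, the liver genes left out and the scalings of W-linked, Z-linked and replicate values were chosen after seeing the data, and normexp on mean spot signals was not run. Leaving out liver genes removed only those of the hepatocyte list and the second liver list. The main counts were 423 probes, 95 genes and 13 lists. They stayed within 1.5 times under quantile normalization, normexp with quantile normalization, no filter, the series matrix values, a variance trend with a robust prior, any fold, Z and W genes left out, liver genes left out (80 genes), the mean of a gene's probes (128 genes) and the averaged high FE arrays, and leaving out saturated probes removed none. Normexp with 75th percentile scaling gave 0 probes and 12 genes, and requiring all 4 arrays above background gave 192 and 59, fewer probes being tested. A 2-fold change without overlap and without p gave 3494 and 447. Leaving out 1 array gave 509 to 6185 probes and 101 to 688 genes, and the largest counts came without low FE replicate 1 or 2, where the spread of that pair drops out and the lone array is assumed to vary like the other group. Samples share only a replicate number, their deviations correlating at 0.19 over 2 pairs. With a replicate block 1511 probes and 219 genes passed, the erythrocyte (adjusted p = 0.0545) and brush border (0.0676) lists were not called and enteric neuron markers were (0.0474). Of 33 named genes that passed, normexp with 75th percentile scaling kept 6, no filter kept 27, and leaving out 1 array kept 28 to 33, with no direction reversed in either.

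With an estimated correlation 0 lists were called, at adjusted p = 0.549 for hepatocyte, interferon, antigen presentation, lipid absorption, pancreas, xenobiotic, oxidative phosphorylation and brush border lists, 0.582 for stromal, lipogenesis and erythrocyte lists, 0.707 for myeloid and 0.732 for ribosomal genes. Fry called 1 list and gave 0.135 for antigen presentation, 0.159 for interferon, lipid absorption, xenobiotic, oxidative phosphorylation and brush border, 0.187 for lipogenesis, pancreas and erythrocyte, 0.204 for stromal, 0.367 for myeloid and 0.709 for ribosomal genes. Ranks gave 0.0548 for myeloid, 0.0914 for erythrocyte and 0.0512 for brush border lists. Ribosomal genes had 0.615 with quantile normalization, 0.361 with normexp and 0.668 with normexp and quantile normalization. Normexp gave 0.267 for oxidative phosphorylation, 0.4235 for myeloid, 0.176 for erythrocyte and 0.0378 for immediate early genes, and with quantile normalization 0.119 for pancreas and 0.0412 for fatty acid oxidation. Without a filter myeloid and brush border lists had 0.0546, and with all 4 arrays above background the pancreas list had 0.121. The variance trend gave 0.0613 for brush border. The mean of a gene's probes gave 0.0862 for pancreas, 0.0534 for erythrocyte and brush border, 0.0217 for enteric neuron and 0.0417 for fatty acid oxidation lists. The averaged high FE arrays gave 0.0510 for erythrocyte and 0.0663 for brush border lists.

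Leaving out 1 array gave adjusted p from 7.36e-04 to 0.212 for pancreas, 1.78e-05 to 0.374 for xenobiotic, 0.0335 to 0.0961 for oxidative phosphorylation, 0.00133 to 0.299 for myeloid, 0.0246 to 0.212 for erythrocyte and 0.0458 to 0.212 for brush border lists. Ribosomal genes ranged from 9.85e-06 without low FE replicate 1 to 0.839 with the direction reversed without low FE replicate 2. Lists not called in the main fit ranged, with 1 array left out, from 7.98e-04 to 0.666 for enteric neuron, 0.00761 to 0.672 for fatty acid oxidation, 1.23e-04 to 0.386 for cholesterol biosynthesis, 7.36e-04 to 0.799 for smooth muscle and 0.0197 to 0.522 for T and NK cell markers. HINTW in low FE replicate 2, where part of its probes were at background, deviated by -7.24 with normexp and -7.91 with normexp and quantile normalization, and Z-linked probes by 0.33 with quantile normalization, 0.62 with normexp and 0.25 with both. The median difference of the low FE pair was 0.36 with normexp and quantile normalization. Where no reason is given, the cause was not tested. Signal over background limits low FE replicate 2 most, with 79.3% of probes above background.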

Other observations

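Some single genes that the text has not described were also higher with high FE, picked here after their values were seen, with no test of them as a group. HPD and FAH, enzymes of tyrosine breakdown, rose by 7.93 and 4.90 on the log2 scale, and CYP8B1, of bile acid synthesis, rose by 4.12. The clotting factor gene F9 rose by 7.65 and F7 was at least 9.70-fold higher (well above background on 1 of 2 low FE arrays), and the gluconeogenic enzyme gene PCK1 rose by 3.81. Of 86 named genes that rose, 11 belong to the hepatocyte list of 25 genes and 75 do not. A gene outside so short a list can still be a liver gene, so the 75 are no count of genes from other tissue.

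The second liver list was written later than the fixed lists, without sight of its values. Of its 16 tested genes, 6 also stood in the fixed lists. All other tests below were chosen after the result was seen. Hepatocyte transcripts were far higher on both high FE arrays. Liver in place of duodenum would remove enterocyte transcripts, and 8 of them had a median of -0.14, from -1.37 to 1.43, which argues against it. An acute-phase response of the duodenum stays open, since the test of it used ALB, TTR, TF and RBP4A (median 8.40), which were called in the pattern itself and decide nothing. Liver RNA within the high FE pool may still account for the pattern, but a second liver list had a median of 0.80 with 68.75% of 16 genes higher and 0 passing, between the bounds set for and against it, so it stays open. Feed efficiency, and expression of these genes by the duodenum itself, stay open and were not tested.

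The low FE arrays differed from each other more than the high FE arrays did. Low signal on low FE replicate 2 would spare bright probes, but over the brightest probes the low FE pair spread 2.40 times as much as the high FE pair, which argues against signal as the whole cause. A thicker muscle layer in low FE replicate 2 is a candidate explanation of part of it, as smooth muscle markers had a median difference of 1.19 (replicate 2 minus replicate 1), with 18 of 19 higher. Cholesterol biosynthesis genes, outside that list, had a median difference of 1.48 as well, enteric neuron markers 0.89 and ribosomal genes 0.78. Some lists went the other way, such as B and plasma cell markers (-0.48) and T and NK cell markers (-0.41). By the cholesterol and ribosomal lists, a shift in this direction was thus not particular to muscle. The neuron and lymphocyte lists cannot tell, since a changed share of the gut layers could move them too. Different birds behind the arrays, including their sex, stay open.

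The array labelled 1 male and 1 female had almost no HINTW signal, except at 1 of 8 probes, which fell by 1.49. Equal parts of male and female RNA would lower HINTW by about 1 on the log2 scale, whereas the median drop of its 8 probes was at least 8.39, with signals at background taken as the lowest signal well above it, which argues against an equal mixture. Low signal on that array would lower other probes of that brightness as well, but over 2640 of them the median difference before scaling was -1.16, which argues against it. RNA almost wholly from males in this array may account for the loss of HINTW and for the Z-linked median of 0.39. At their brightest probes other W-linked genes did not show such a loss, and neither did HINTW, whose brightest probe fell by 1.49. In low FE replicate 2 SPIN1L had -0.96 against the other 3 arrays. Its other probes had -3.75 and -0.61. SMAD7B at -4.31 lay within the range of the other arrays, and UBAP2L2 at 0.31 was highest there. Brightest probes alone thus cannot tell whether these genes were lost. With different sexes behind them, the 2 low FE arrays would not be parts of 1 pool, and the labels themselves were not tested.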
